A study of Mus musculus with 4 samples.

How the data were processed

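RNA expression was measured in mouse cortex and hippocampus on Affymetrix Mouse Genome 430 2.0 arrays, 3′-biased oligonucleotide arrays on which a gene is read by 1 or more probe sets. There were 4 arrays, 1 for each combination of tissue and treatment (anti-let7 or PBS). Per the labels' protocols, total RNA was extracted with TriZol, 2 µg was labelled with biotin, and each sample went on 1 array. The labels do not say how anti-let7 was given, for how long, whether a sample is 1 animal or a pool, or whether the cortex and the hippocampus of a treatment came from the same animals. No strain, batch or scan date was given in the sources used here.

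The deposited values are log2 expression values made by the authors with RMA (robust multi-array average), per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of a set on the log2 scale. The RMA version and the set of arrays normalized together are not given in the sources used here. The values fit that description: they ran from 3.46 to 15.3, each array's median was between 7.21 and 7.22, and the sorted values of the 4 arrays lay within 0.086 of their mean. Because quantile normalization gives every array the same distribution, a change that moved most genes one way would have been removed. The values carry no detection call and no depth, so a low value is only a low value, and log2 differences of dim probe sets understate the change. The number of arrays limits the precision.

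The table held 45101 probe sets. Leaving out 64 control probe sets, GEO's platform annotation named exactly 1 gene for 34945, several for 932 and none for 9160. Symbols were updated through the gene identifier to the RefSeq table of assembly GRCm38.p6, which held 34741 of the 34945. No genome build applies to the expression values, so no coordinates are given. Probe sets with several genes or none were not named. The 40% of probe sets with the lowest mean over the 4 arrays (below 6.51) were left out, and each gene was then read on its brightest remaining probe set, which left 12853 genes. The probe sets of a gene are not independent samples and were used only to check the direction. Probe sets whose names end in x_at or s_at can bind related transcripts.

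With 1 array per group, the difference between anti-let7 and PBS within a tissue has no replicate error, and it is given as a value without a test. The only test of treatment that leaves an error term is an additive model over both tissues (limma lmFit and eBayes with tissue as a covariate), in which the disagreement between the 2 tissues is the error. It has 1 residual degree of freedom, to which eBayes added 2.18 prior degrees of freedom. The same model tested hippocampus against cortex. Genes with a Benjamini-Hochberg adjusted p of at most 0.05 were called. These p-values measure the spread between 2 tissues, not between animals, and an effect of the animals shared by both tissues would be called like an effect of treatment. The tissue-specific part of the treatment difference has no error term at all.

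There were 17 gene lists and 16 marker lists, fixed before the data were examined. A list's median log2 difference, averaged over the tissues gene by gene, was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart below the 2.5th or above the 97.5th percentile. This describes these arrays and is not a p-value: genes of a pathway vary together more than random genes do, so a list can stand apart without a treatment effect. List members were also counted by the limma test, adjusted over all genes and adjusted over the list alone. Lists with under 3 measured members were not rated, which left out the blood cell markers.

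Named genes followed a rule set before the data were examined. It took the 12 genes higher and the 12 lower in both tissues with the largest smaller difference, the 4 highest and the 4 lowest in each tissue, up to 4 members of each list with the largest mean difference, and the let-7 target and mTORC1 list members different by at least 0.32 on the log2 scale the same way in both tissues. For hippocampus against cortex it took the 8 genes with the largest difference in each direction, and for the tissue-specific part the 4 largest in each direction. Predicted genes without a regular symbol were not named. Other genes named were chosen after their values were seen, and this is said where they appear.

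The fit was tested on simulated data: 4 arrays of the 12853 genes with the real means and the fitted spread, and 200 genes changed by known folds. For the common treatment effect it recovered 8.96% of the genes changed 1.5-fold, 71.6% of those changed 2-fold and 100% of those changed 4-fold, and called 4 unchanged genes. These shares hold for the simulated noise, which was independent between arrays and gave more large opposite differences than the real arrays. Of 100 unchanged lists of 20 genes, 5 were rated as standing apart. That share follows from the percentile cut-offs, because the simulated genes were independent, and it does not rate lists whose members vary together. The alternatives were no filter on dim probe sets, a filter of 60%, the mean of a gene's probe sets, cyclic loess, median centring, an intensity trend or robust eBayes, other fold thresholds, and each tissue alone. Added after seeing the data were the removal of x_at and s_at probe sets and the removal of the genes of all preset lists. A planned comparison of genes with and without let-7 seed sites in their 3′ UTR was not run, because no transcript sequences were used here. Work was done in R 4.3.3 with limma 3.58.1; plots were drawn in Python 3.11.15 with matplotlib 3.10.9.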

Results

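The expression of 12853 genes was compared between mouse brain tissue treated with anti-let7, an inhibitor directed against the let-7 family of microRNAs, and tissue treated with PBS, the saline control. Each treatment was represented by 1 cortex and 1 hippocampus array, 4 arrays in all and 1 per group. The series title sets the experiment in the context of let-7 and autophagy. MicroRNAs themselves are not read by these arrays, so the inhibition of let-7 was not measured directly. Across all probe sets the 2 cortex arrays correlated at 0.996 and the 2 hippocampus arrays at 0.995, above the correlation of the 2 PBS arrays (0.992) and of the 2 anti-let7 arrays (0.991).

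The first question was whether the arrays separate the 2 regions as labelled. All 8 measured hippocampal markers were higher in hippocampus than in cortex by the limma test. They included Dsp, a desmosomal gene of dentate granule cells (log2 difference 4.25, SE 0.090), Spink8 (3.87, SE 0.21), Lct (3.65, SE 0.082), C1ql2 (3.60, SE 0.18) and Fibcd1 (2.84, SE 0.11). Of 9 measured cortical markers, 7 were higher in cortex, among them Lamp5 (-1.81, SE 0.057), the cortical transcription factor gene Tbr1 (-1.39, SE 0.042) and Rorb (-1.11, SE 0.072), and 2 were higher in hippocampus. The genes with the largest excess in cortex included Myl4, a myosin light chain (-3.26, SE 0.14), and Rspo1, a secreted Wnt agonist (-2.85, SE 0.13). In all, 1061 genes were higher in hippocampus and 1202 higher in cortex at an adjusted p of at most 0.05 in limma (n = 2 arrays per region). Without the filter on dim probe sets these counts were 361 and 455.

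The second comparison asked which genes differed between anti-let7 and PBS in each tissue. In cortex 181 genes were at least 1.5-fold higher and 34 at least 1.5-fold lower in the anti-let7 array. In hippocampus 229 were higher and 108 lower. Among the analysed genes with a regular symbol, the 4 with the largest excess in both tissues were the interferon-induced genes Ifi27l2a (14.4-fold in cortex, 7.36-fold in hippocampus), Oasl2 (8.27-fold and 7.70-fold), Ifit1 (6.52-fold and 8.72-fold) and Usp18 (6.49-fold and 6.59-fold). Their PBS values lay near or below the filter value of 6.51, from 5.92 for Oasl2 in hippocampus to 6.82 for Ifit1 in cortex. The sizes of these differences are therefore uncertain. The 2 genes with the largest deficit in both tissues were Gh, growth hormone (10.9-fold lower in cortex, 19.8-fold in hippocampus), and Prl, prolactin (3.87-fold and 10.5-fold lower). The anti-let7 values of Prl (6.01 in cortex and 5.64 in hippocampus) lay below the filter value, so the size for Prl is uncertain. The 3 other probe sets of Gh gave larger log2 differences, from -4.35 to -4.26 in cortex and from -5.33 to -5.08 in hippocampus, with anti-let7 values of 4.46 to 4.60, near the low end of the scale, so the size of this difference is uncertain. Next in cortex came Etnppl, an astrocytic phospholyase (2.74-fold lower), and Erdr1 (2.45-fold lower). Next in hippocampus came Ttr, transthyretin (6.88-fold lower), and the potassium channel gene Kcnj13 (4.68-fold lower), both made by the choroid plexus, and neither was lower in the cortex of the anti-let7 sample. These are differences between single arrays, with no replicate check.

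The differences in the 2 tissues, which share no array, went together. Of the genes at least 1.5-fold different in both tissues, 140 were higher in both, 16 were lower in both and 0 went in opposite ways. Among the unchanged genes of the simulated arrays, 24 went the same way by that much and 18 opposite ways. The simulated noise was independent between arrays and held no effect shared by the tissues. With 18 opposite ways against 0 in the real arrays, its extremes were wider, so the simulated 24 is not a matched no-change value. At a log2 difference of at least 0.32 in both, 580 went the same way and 16 opposite ways. Across genes the cortex and hippocampus differences correlated at Pearson r = 0.71 and Spearman rho = 0.60. Genes are not independent replicates, and no batch was given within which to repeat the correlation. An effect of the animals shared by both tissues would raise the same-way count and the correlation just as treatment would. Of the 156 genes different the same way, 64 were read by at least 2 probe sets, and for 50 of these every probe set went the same way in both tissues. Without the genes of all preset lists, an alternative added after seeing the data, 110 were higher in both, 15 lower in both and 0 opposite.

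**Figure D1:**
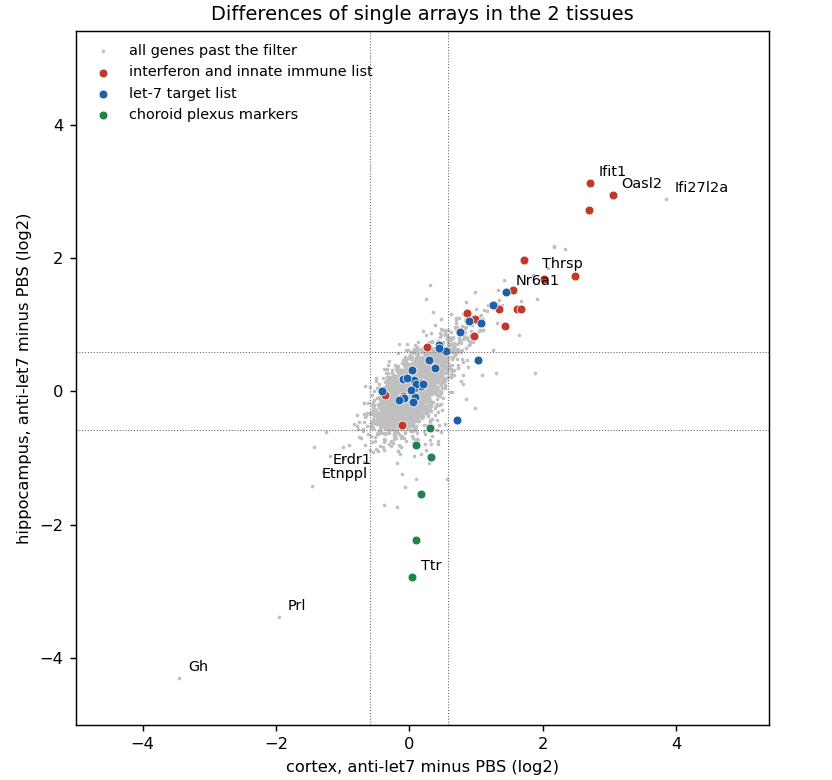
Each point is a gene past the filter, with the log2 difference between the anti-let7 and the PBS array in cortex (x axis) and in hippocampus (y axis); dotted lines mark 1.5-fold, and colours mark 3 preset lists. Interferon genes such as Oasl2 (3.05 and 2.94) and let-7 targets such as Nr6a1 (1.46 and 1.48) lie near the diagonal, while choroid plexus genes such as Ttr (0.05 and -2.78) are lower in hippocampus alone.

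The genes higher in both tissues were led by interferon-induced genes. By the limma test over both tissues, Oasl2 (log2 differences 3.05 in cortex and 2.94 in hippocampus, SE of their mean 0.049, adjusted p = 0.026), Usp18, which encodes an inhibitor of interferon signalling (mean 2.71, SE 0.040, adjusted p = 0.026), Lgals3bp (2.18, SE 0.040, adjusted p = 0.026), Rtp4 (2.17, SE 0.040, adjusted p = 0.026) and the guanylate-binding protein gene Gbp6 (1.96, SE 0.073, adjusted p = 0.0498) rose. Kcne1l, a potassium channel subunit gene, rose by 2.23 (SE 0.066, limma adjusted p = 0.0453) and Thrsp, a regulator of lipid synthesis, by 1.80 (SE 0.051, limma adjusted p = 0.0453), and all 3 probe sets of Thrsp went the same way. Ifi27l2a (3.36, SE 0.27), Ifit1 (2.91, SE 0.12), the chemokine gene Cxcl10 (2.10, SE 0.22), Bst2 (1.86, SE 0.10) and Ifit3 (1.85, SE 0.080) had mean differences as large but missed the threshold, with limma adjusted p between 0.0519 for Ifit1 and 0.0815 for Cxcl10. Altogether 23 genes rose and 3 fell at an adjusted p of at most 0.05, with n = 2 arrays per treatment. The number of calls depended strongly on the processing, from 0 without the filter on dim probe sets to 561 with an intensity trend in eBayes, while 3396 genes had an unadjusted p under 0.05. With the labels of the hippocampus arrays swapped, limma called 0 genes and 41 had an unadjusted p under 0.05; in that fit the difference shared by the tissues goes into the error, so it is stricter than a test on unchanged arrays.

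Of the preset interferon and innate immune list, 20 of 26 genes were measured, and 14 of them were at least 1.5-fold higher in both tissues and 0 at least 1.5-fold lower. The median of the list was 1.39 in cortex and 1.20 in hippocampus, and none of 10000 matched random lists had a median as high. By limma, 4 members rose when adjusted over all genes (Oasl2, Usp18, Ifitm3 and Oas1a, the last 2 named after their values were seen) and 16 when adjusted over the list alone. The 4 members lower in both tissues, named after their values were seen, were Cd14 (-0.36 in cortex and -0.05 in hippocampus), Tnf (-0.11 and -0.51), Il1b (-0.11 and -0.10) and Myd88 (-0.10 and -0.08), none of which passed the test. Of the list of reactive glia and complement genes, 16 were measured, 5 were at least 1.5-fold higher in both tissues and 0 lower, with a median of 0.45 in the mean over tissues and 0 of 10000 random lists as high. Adjusted over all genes, 1 member rose, the MHC class I gene H2-D1 (1.19 in cortex, 1.30 in hippocampus); adjusted over the list alone, 11 rose and 1 fell. Osmr, the oncostatin M receptor (0.83 and 0.89), Lgals3, galectin-3 (0.88 and 0.76), and the astrocyte filament gene Gfap (0.85 and 0.65) were next in size. The microglial markers moved alongside, with a median of 0.25 in cortex and 0.35 in hippocampus over 7 measured genes and 4 of 10000 random lists as high, led by the complement genes C1qb (0.60 and 0.82) and C1qa (0.52 and 0.63). Of the 7, 5 rose adjusted over the list alone, and adjusted over all genes 0 did.

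The let-7 target list, known targets of the microRNA family that anti-let7 is directed against, was higher as a group in both tissues. Of 39 genes, 26 were measured. Of these, 10 were higher by a log2 difference of at least 0.32 in both tissues, 5 at least 1.5-fold, and 0 were lower by 0.32 in both. The median was 0.19 in cortex and 0.19 in hippocampus, and 0 of 10000 matched random lists had a median as high. By limma, 3 rose when adjusted over all genes: Nr6a1, an orphan nuclear receptor (1.47, SE 0.041, adjusted p = 0.0453), Dicer1, the microRNA-processing nuclease (1.27, SE 0.042, adjusted p = 0.0498), and Cdc34, a ubiquitin-conjugating enzyme (1.05, SE 0.043, adjusted p = 0.0498). For Nr6a1 3 of 4 probe sets went the same way in both tissues, and for Dicer1 2 of 2. These 3 calls were lost without the filter on dim probe sets, where 0 genes were called. Of all 26 calls for treatment, 11 were made again with robust eBayes and 10 without x_at and s_at probe sets. Dicer1 and Cdc34 were among the calls closest to the threshold. Adjusted over the list alone, 11 rose and 0 fell. The other members higher by at least 0.32 in both tissues were the TGF-β receptor gene Tgfbr1 (0.90 in cortex, 1.06 in hippocampus), the oncogene Nras (0.76 and 0.88), Arid3b (1.02 and 0.47), Mycn (0.55 and 0.60), Plagl2 (0.45 and 0.70), Gnptab, which acts in the sorting of lysosomal enzymes (0.45 and 0.65), and Nr2e1 (0.38 and 0.35). All 3 probe sets went the same way for Nras and for Gnptab, but 2 of 3 did for Mycn and 1 of 2 for Plagl2. Not every member went this way: the fetal let-7 target Hmga2 differed by -0.41 in cortex and 0.0045 in hippocampus, Fign by 0.71 and -0.43, Igf2bp3 by -0.08 and -0.10, and Igf1r by -0.15 and -0.13, all 4 chosen after their values were seen. Lin28a, Lin28b, Trim71, Myc and 4 other members lay below the filter, and 5 were not analysed here.

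**Figure D2:**
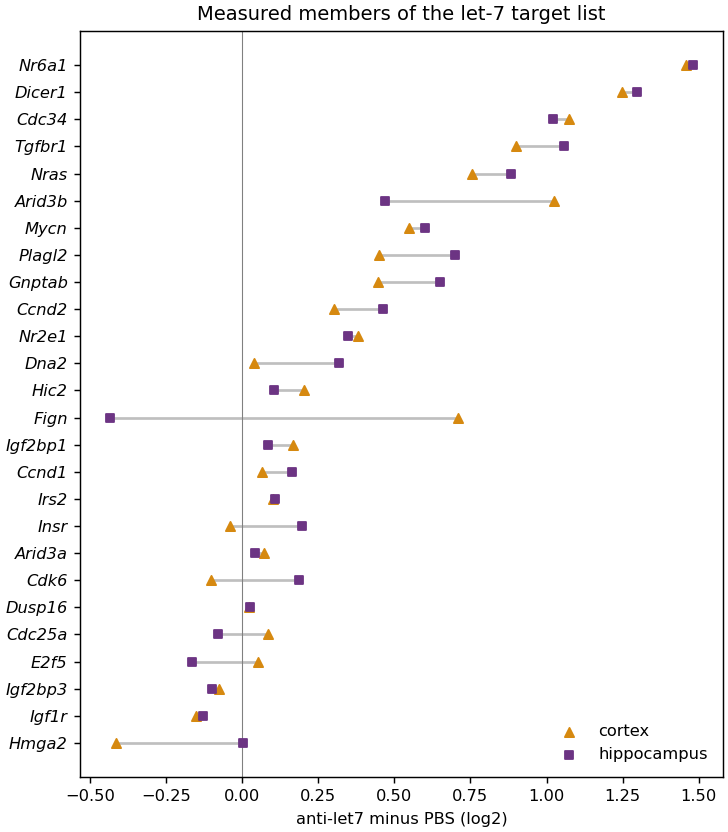
Each row is a measured member of the let-7 target list, with the log2 difference between the anti-let7 and the PBS array in cortex (triangle) and hippocampus (square), single arrays without error bars. Nr6a1 (1.46 and 1.48), Dicer1 (1.30 in hippocampus) and Cdc34 (1.07 and 1.02) lead, and Hmga2 (-0.41 and 0.0045) is last.

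The microRNA machinery list did not stand apart as a whole (median 0.03 in the mean over tissues, at the 76.1th percentile of random lists, 16 measured), but 3 members were at least 1.5-fold higher in both tissues. These were Dicer1, Tarbp2, a Dicer partner (0.83 and 0.95), and the Argonaute gene Ago2 (0.63 and 0.62); all 3 rose when adjusted over the list alone, and Dicer1 alone when adjusted over all genes. Of the 16 measured members, 7 were higher in both tissues by any amount and 2 lower in both, among the latter Ago4 (-0.25 and -0.13).

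The series title names autophagy, and the preset autophagy list did not stand apart. Of 43 genes 41 were measured, with a median of -0.03 in cortex and 0.01 in hippocampus, at the 23.9th percentile of random lists in the mean over tissues, where the mean of the members was 0.02 and the median -0.01. No member passed limma adjusted over all genes. The 2 that rose adjusted over the list alone were Stx17, the syntaxin of autophagosome fusion (0.54 and 0.63, all 4 probe sets), and Wipi1, a phosphoinositide-binding autophagy protein (0.55 and 0.45, 4 of 5 probe sets). Atg16l1 (0.35 and 0.24) and Atg5 (-0.27 and -0.24) were next in size. The amino acid sensing and mTORC1 list was likewise near 0, with a median of -0.01 in cortex and 0.02 in hippocampus over 39 of 42 genes, at the 69.9th percentile, and the median over tissues, 0.01, was below 0 after median centring or cyclic loess. Only 1 member rose adjusted over the list alone, Fnip2, a folliculin partner (0.60 and 0.72), and adjusted over all genes 0 did; Tbc1d7 (0.31 and 0.35), the Rag GTPase gene Rragd (0.22 and 0.29) and the mTOR-binding gene Deptor (-0.21 and -0.42) followed. Map4k3, Rragb and Rps6kb1 were not analysed here. The lysosome and TFEB target list had a small shift, with a median of 0.04 in cortex and 0.07 in hippocampus over 33 genes, at the 98.7th percentile in the mean over tissues, but at the 97.0th in cortex alone, where it did not stand apart. In the list taken alone, 6 rose and 1 fell, led by Gusb, β-glucuronidase (0.75 and 1.09); adjusted over all genes, 0 did. The cathepsin genes Ctsz (0.35 and 0.48), Ctsa (0.38 and 0.39) and Ctss (0.27 and 0.37) followed.

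Cholesterol synthesis genes were higher as a group, with a median of 0.20 in cortex and 0.36 in hippocampus over 16 measured genes and 0 of 10000 random lists as high. Of these, 15 were higher in both tissues and 0 lower in both. Adjusted over the list alone, 10 rose and adjusted over all genes 0 did, the largest being Idi1 (0.48 and 0.52), Mvd (0.49 and 0.41), Insig1 (0.39 and 0.51) and Fdft1 (0.36 and 0.43). Cell cycle genes had a median of 0.06 in cortex and 0.23 in hippocampus over 17 genes, at the 99.9th percentile in the mean over tissues, but at the 97.3th with 60% of probe sets left out and the 93.2th in cortex alone, where it did not stand apart. Adjusted over the list alone 3 rose and adjusted over all genes 0 did; Top2a (0.50 and 0.74), Ccna2 (0.31 and 0.48) and Mcm6 (0.38 and 0.33) were among the largest, with the proliferation marker Mki67 at 0.36 and 1.19. The insulin, IGF and PI3K list had a median of -0.06 in each tissue over 22 genes, at the 2.02th percentile, with Igf2 (-0.54 and -0.91) and Igfbp2 (-0.06 and -0.60) lowest. By limma adjusted over the list alone, Irs1 rose, and Igf2, which is also a preset meningeal marker, and Igfbp6 fell. The list did not stand apart in either tissue alone, nor in the mean over tissues with the mean of probe sets (10.2th), 60% of probe sets left out (2.99th) or shared members left out (2.85th). The stress and unfolded protein response list had a median of -0.05 in cortex and -0.12 in hippocampus over 25 genes, at the 1.64th percentile in the mean over tissues and the 5.85th in cortex alone. When adjusted over the list alone, 4 fell and 1 rose; the chaperone-related genes Sdf2l1 (-0.49 and -0.33), Creld2 (-0.37 and -0.37) and the transcription factor gene Xbp1 (-0.26 and -0.35) were lower, whereas the mTORC1 inhibitor gene Ddit4 (0.62 and 0.62) was higher. Oxidative phosphorylation genes had a median of 0.04 in each tissue over 27 genes, at the 98.8th percentile, and 0 passed adjusted over the list alone.

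The genes lower in both tissues were fewer. By limma, Etnppl (-1.43, SE 0.042, adjusted p = 0.0453), Erdr1 (-1.29 in cortex and -1.21 in hippocampus, SE of the mean 0.047, adjusted p = 0.0498) and the glutathione S-transferase gene Gstm1 (-1.01, SE 0.040, adjusted p = 0.0498) fell. For Gstm1 all 4 probe sets went the same way, and for Etnppl 1 of 2. Erdr1 and Gstm1 were read on x_at probe sets. The number of genes called lower was 1 with robust eBayes, 1 without x_at and s_at probe sets and 0 without the filter on dim probe sets. Gh (-3.88, SE 0.24) and Prl (-2.67, SE 0.40) had the largest mean differences but missed the threshold, with limma adjusted p of 0.062 and 0.102. Their levels in the anti-let7 arrays were 6.72 and 6.65 for Gh and 6.01 and 5.64 for Prl, near or below the filter value of 6.51, against 10.17 and 10.96 and against 7.96 and 9.02 in the PBS arrays. Other genes among the 16 lower in both tissues were the transporter gene Abca8a (-1.18 in cortex, -0.97 in hippocampus), Mid1 (mean -0.91), Prg4 (-0.91 and -0.81), Rab9b (-0.72 and -0.70), the endothelial gene Plvap (-0.75 and -0.69), Ddit4l (-0.66 and -0.80) and the chemokine gene Ccl28 (-0.62 and -0.64).

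Marker lists of other cell types and regions moved as well. Neuronal and oligodendrocyte marker lists had slightly lower medians: over tissues, -0.13 for excitatory neurons, -0.12 for inhibitory neurons and -0.11 for oligodendrocytes, at the 1.22th, 0.92th and 1.74th percentiles. Adjusted over the list alone, 1 excitatory marker rose and 2 fell, 0 inhibitory markers rose and 2 fell, and 0 oligodendrocyte markers passed. The excitatory marker Slc17a7 was higher in both tissues (0.23 and 0.26). The excitatory list did not stand apart in hippocampus alone (3.14th) or without members shared with another list (5.11th), and the oligodendrocyte list did not with the mean of probe sets (4.45th) or without x_at and s_at probe sets (2.62th), an alternative added after seeing the data. Astrocyte markers (-0.09, 2.73th percentile), oligodendrocyte precursor markers (-0.09, 5.97th) and vascular markers (-0.07, 12.5th) did not stand apart in the mean over tissues, though the astrocyte and the precursor markers did in cortex alone (2.24th each), and the astrocyte markers also with 60% of probe sets left out (2.43th) and with the mean of probe sets (2.30th). Among astrocyte markers 1 rose and 3 fell adjusted over the list alone, and Aqp4 was higher in both tissues (0.44 and 0.48). Hippocampal markers had a median of -0.18 in cortex and -0.28 in hippocampus. Of the 8 measured, 5 were lower in both tissues, led by C1ql2 (-1.24 and -0.60), while Spink8 was higher in hippocampus (0.57). In the cortex arrays Dsp (5.21 with anti-let7 and 5.33 with PBS), Lct (5.73 and 6.25) and Fibcd1 (5.85 in each) lay below the filter value of 6.51. The cortex median thus rests partly on dim values. Cortical markers had lower medians too (-0.11 and -0.29), but did not stand apart with the mean of probe sets (5.34th percentile). In these 2 lists 0 members fell adjusted over all genes, and 4 and 3 adjusted over the list alone.

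The third comparison asked where the treatment difference was unlike between the tissues. The choroid plexus markers had a median of 0.14 in cortex and -1.27 in hippocampus, and all 6 measured markers were lower in the anti-let7 hippocampus array. Ttr, Kcnj13 and Kcne2, a channel subunit gene of the choroid plexus (0.20 and -1.57), were among the 4 genes with the most negative hippocampus-minus-cortex value, with Trh, thyrotropin-releasing hormone (0.57 and -1.31). Striatal markers followed with a median of -0.01 in cortex and -0.48 in hippocampus, led by Penk, proenkephalin (-0.18 and -1.73). The genes more positive in hippocampus were Igfbpl1, expressed in immature neurons (0.31 and 1.60), Cpne9 (-0.16 and 0.72), Mki67 (0.36 and 1.19) and Ric3 (-0.30 and 0.46). Among activity-dependent genes the median was 0.15 in cortex and 0.00 in hippocampus over 27 genes, and the list stood apart in cortex alone, with Arc at 0.87 and 0.47, Sik1 at 0.88 and 0.37, Junb at 0.68 and 0.25 and Dusp1 at 0.80 and 0.11; 0 passed adjusted over the list alone. None of these tissue-specific differences could be tested, since the design has no replicate within tissue and treatment.

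**Figure D3:**
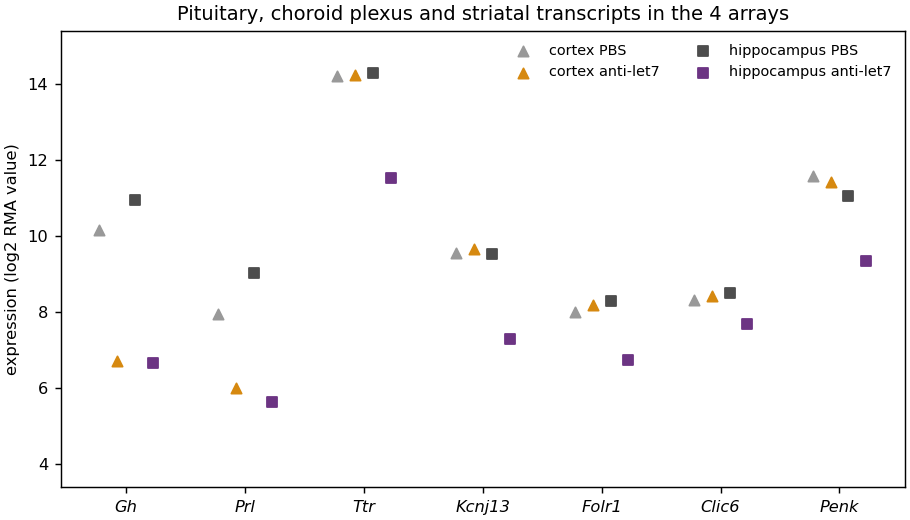
Log2 RMA values of 7 genes in each of the 4 arrays (triangles, cortex; squares, hippocampus; grey, PBS; colour, anti-let7). Gh and Prl are lower in both anti-let7 arrays, while Ttr (14.26, 14.21, 14.31 and 11.53 in cortex anti-let7, cortex PBS, hippocampus PBS and hippocampus anti-let7) and the other choroid plexus genes are lower in the anti-let7 hippocampus array alone.

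Across the 33 preset lists, 32 had enough measured genes to be rated, and 17 stood apart, 8 higher and 9 lower, where 1.6 would be expected among independent random genes. The ribosomal protein list (median 0.00, 17 genes, 56.6th percentile), the heat shock list (-0.06, 13 genes, 5.88th), the glucocorticoid-responsive list (0.01, 15 genes, 69.3th) and the sex-linked genes (0.11, 4 genes, 89.5th) did not. The glucocorticoid-responsive list went in opposite ways in the 2 tissues, with a median of -0.17 in cortex and 0.09 in hippocampus, and stood apart in each alone (0 of 10000 random lists as low in cortex, 97.9th percentile in hippocampus); 4 members rose and 4 fell adjusted over the list alone. The ribosomal median was below 0 after median centring. The markers of meninges (-0.06, 16.7th), ependyma (0.11, 90.1th), thalamus (-0.05, 21.2th) and hypothalamus (-0.17, 3.03th) did not stand apart in the mean over tissues either. Under alternatives the meningeal markers did with 60% of probe sets left out (-0.45, 0.01th) and were at 0.08 without members shared with another list, and the hypothalamic markers did with the mean of probe sets (2.35th) and cyclic loess (2.17th). In hippocampus alone the meningeal (0.75th), thalamic (1.80th) and hypothalamic (1.37th) markers did, as did the heat shock list in cortex alone (1.36th). Of the blood cell markers only Alas2, an erythroid heme enzyme, was measured (1.26 in cortex and 0.62 in hippocampus).

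**Figure D4:**
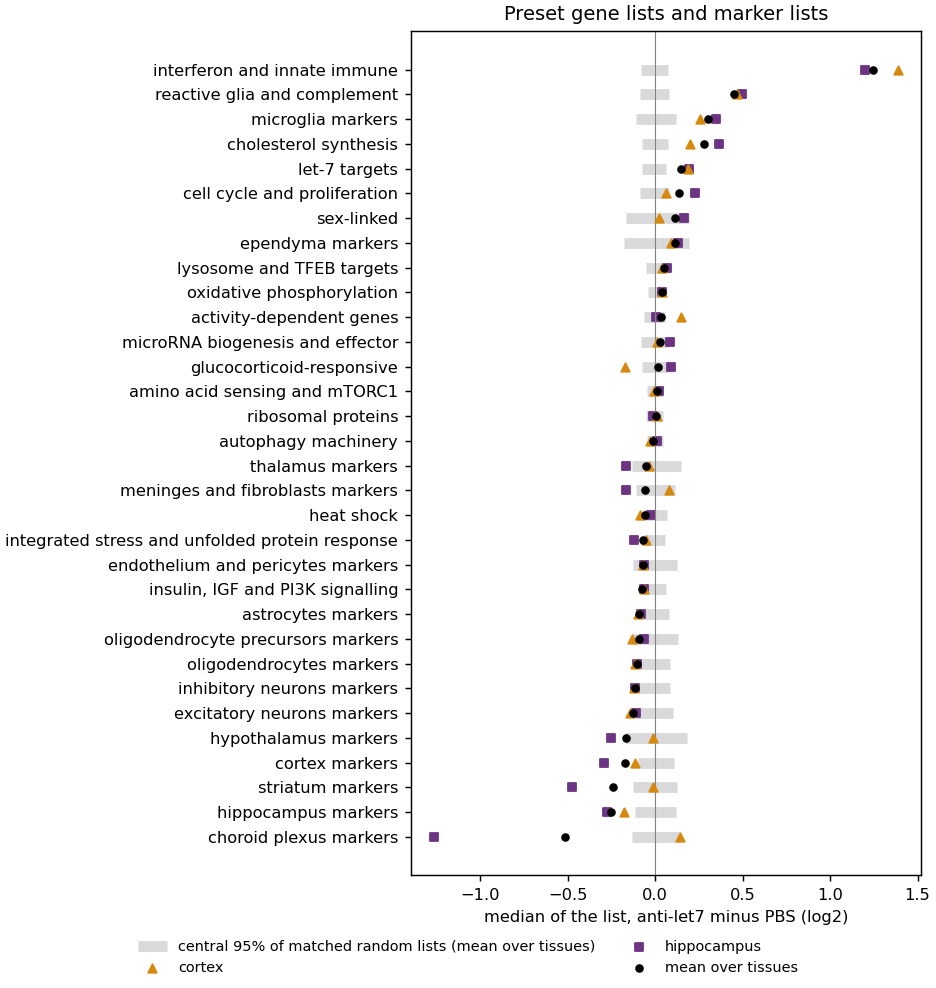
Median log2 difference between anti-let7 and PBS of each rated list, in cortex (triangles), in hippocampus (squares) and in the mean over the tissues (dots); grey bars span the medians of 10000 matched random lists for the mean, without the lowest and highest 2.5%. The interferon list (1.39 in cortex and 1.20 in hippocampus) lies farthest above its bar, the choroid plexus markers (-0.52) farthest below, and the autophagy list (-0.01) within it.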

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

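The test of microglial share was chosen after the results were seen, and a difference between animals was named as an explanation afterwards but could not be tested; the tests of the further choroid plexus and pituitary genes were written before those genes' values were seen, except that Pomc had been seen.

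Interferon-responsive genes were higher in both anti-let7 arrays, with a list median of 1.39 in cortex and 1.20 in hippocampus. A larger share of microglia, with expression per cell unchanged, would raise all microglial markers about as much. The highest of the 7 measured markers, C1qb, had a mean difference of 0.71 (0.60 in cortex and 0.82 in hippocampus). That argues against such a larger share as the whole cause. Whether expression per microglial cell changed was not tested. A response to the inhibitor, to its delivery, or an immune state of the animals sampled that had nothing to do with the treatment remain open, since there is 1 array per group and no control oligonucleotide among the samples analysed here.

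The choroid plexus markers differed in sign between the tissues, a difference that was not tested, with hippocampus-minus-cortex values of -2.83 for Ttr, -2.33 for Kcnj13, -1.72 for Folr1, -0.91 for Clic6 and, outside the list, -1.77 for Kcne2. A candidate explanation is less choroid plexus tissue in the anti-let7 hippocampus sample. Of 12 further choroid plexus genes, 7 passed the filter and all 7 were lower in that array, with a median of -0.47 against 0.12 in cortex, but only 3 were lower by at least 0.5 (42.9%, exact binomial 95% interval 9.90 to 81.6%). Set in advance as evidence against the explanation was a share of fewer than 1 in 2 or a median above -0.25. The share, 3 of 7, met its bound, and the median of -0.47 did not meet its own. Cldn2 (-0.47) and Wfdc2 (-0.45) fell just short of 0.5. The interval was brought in after the share was seen. It treats genes read on the same arrays as independent trials, which they are not, so it does not overturn the result for the share. Because all 7 were lower, the explanation is not excluded either. The preset markers had a median of -1.27 in that array, and striatal markers were lower there too (-0.48). Ttr was as high in the cortex arrays (14.26 with anti-let7 and 14.21 with PBS) as in the PBS hippocampus array (14.31). Kcnj13 was likewise (9.67 and 9.57 against 9.52). The preset median in cortex was 0.14, so an effect on the choroid plexus shared by both anti-let7 samples is not seen. An effect on the choroid plexus in the hippocampus sample alone stays open too.

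Gh and Prl were lower in both anti-let7 arrays. Pituitary tissue carried into the PBS samples would bring other abundant pituitary transcripts with it. The median of Pomc, Cga, Lhb and Tshb, without a filter, was -0.23 in cortex and -0.28 in hippocampus. A median above -0.25 in both tissues had been set in advance as evidence against this explanation. That held in cortex but not in hippocampus, so this median decides nothing. The mean levels of Cga (6.13), Lhb (6.41) and Tshb (5.91) lie below the filter value of 6.51, where log2 differences can understate a change. Cga (-1.01 and -0.67) and Lhb (-0.33 and -0.49) were lower, Tshb (0.25 and 0.05) was not, and Pomc hardly differed (-0.12 and -0.07). Carried-over tissue and a change in hormone transcripts within the brain cannot be told apart with these 4 transcripts.

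Among the genes taken by the naming rule, to which this search was limited, others whose difference had opposite signs in the 2 tissues, by at least 1.5-fold in all and untested, were Trh (-1.89 for hippocampus minus cortex), Cpne9 (0.87), Tnnc1 (-0.82), Ric3 (0.76), Cabp7 (0.75) and Spink8 (0.73). Among the control probe sets, outside the main measurement, those for the 5′ and the middle part of 18S ribosomal RNA were higher by 1.28 and 1.09 in the cortex anti-let7 array than in the cortex PBS array, against -0.34 and -0.15 in hippocampus. The hybridization control probe sets for BioB, BioC, BioD and Cre were also higher in the cortex anti-let7 array, by 0.07 to 0.37. In hippocampus they differed by -0.16 to 0.11, so the 2 cortex arrays were not technically alike. The β-actin 5′-to-3′ difference was between -0.57 and -0.53 in all 4 arrays. Of 4114 probe sets past the filter with several genes or none, 24 were at least 1.5-fold higher in both tissues, 6 lower in both and 0 opposite.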

How the results depend on the processing

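The number of genes that rose and fell by the limma test of treatment (23 and 3) moved under every alternative: 0 and 0 without the filter on dim probe sets, where the smallest adjusted p was 0.0741 and 3647 genes had an unadjusted p under 0.05, 323 and 108 with 60% left out, 193 and 30 with the mean of a gene's probe sets, 148 and 22 with cyclic loess, 149 and 24 with median centring, 390 and 171 with an intensity trend and 10 and 1 with robust eBayes. With alternatives added after seeing the data it was 9 and 1 without x_at and s_at probe sets and 2 and 0 without the genes of all preset lists. The smallest adjusted p lay between 0.00457 and 0.0741 over all of these, and the cause was not tested. The 26 genes were all called again with the mean of probe sets, cyclic loess, median centring and the intensity trend. With 60% left out 20 of them were called again, with robust eBayes 11, and without x_at and s_at probe sets 10. For hippocampus against cortex, the calls were 361 and 455 without the filter, and 1705 higher in hippocampus with an intensity trend. Fold counts moved with fewer genes tested (60% left out: 21 lower in cortex, 150 higher and 65 lower in hippocampus) and with the fold threshold. At 2-fold there were 48 higher and 7 lower in cortex, 60 and 18 in hippocampus, and 37 and 4 in both; at a log2 difference of 0.32 there were 430 and 150 in both, with 16 opposite. No other fold count moved by over 1.5 times. Pearson r across genes between the tissues was 0.60 to 0.77. The let-7 target list (median 0.13 to 0.27) and the interferon list (1.03 to 1.45) stood apart under every alternative run, and the autophagy (-0.03 to 0.01) and mTORC1 lists (-0.01 to 0.02) under none. Between 15 and 19 lists stood apart. Of the other lists, 15 values lost and 13 gained this rating, and 2 reversed: in cortex alone the glucocorticoid-responsive list was at -0.17 and the choroid plexus markers at 0.14. The median of all genes was -0.013 in each tissue after median centring and -0.0070 in cortex and -0.0081 in hippocampus after cyclic loess, against -0.0032 and 0.00073. No replicate could be left out, because 3 arrays leave no residual degree of freedom. No paired analysis by animal was possible because the labels do not link arrays to animals; the additive model already compares the arrays within each tissue. The let-7 seed site comparison was not run. No detection calls were used, so what signal over background limits is unknown.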

Other observations

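The MHC class I genes H2-K1 (1.32 in cortex and 1.31 in hippocampus) and H2-D1 (1.19 and 1.30), the latter also a member of the preset reactive glia list, rose by the limma test over all genes, and both were read on x_at probe sets. They prompted a list of 15 MHC class I pathway genes, drawn up before most of the others had been seen. Without these 2, 7 were measured, of which 4 were at least 1.5-fold higher in both tissues, 0 at least 1.5-fold lower, and 0 passed limma over all genes, with a median of 0.63 in each tissue. The 4 were the immunoproteasome genes Psmb8 (1.04 and 0.91) and Psmb9 (0.68 and 0.63), the peptide transporter gene Tap1 (0.73 and 0.63) and B2m (0.63 and 0.78), while Psmb10 was not higher (-0.10 and -0.19).

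Other genes that rose by limma over both tissues, with mean log2 differences in parentheses, chosen for mention after their values were seen, were the guanylate-binding protein gene Gbp7 (1.36), the tripartite motif genes Trim30a (1.18) and Trim34a (1.08), the leukocyte surface gene Cd52 (1.20 in cortex and 1.29 in hippocampus), Gramd3 (1.34), the sodium-proton exchanger gene Slc9a9 (1.24), Sema4f (1.09), Ms4a6b (1.11) and Samd9l (1.04). Erdr1 and Mid1, both lower in the anti-let7 arrays, are neighbouring genes on the X chromosome. The male-specific gene Eif2s3y was at 9.70 and 9.45 in the cortex arrays and 9.79 and 9.51 in the hippocampus arrays.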
